A study of Mus musculus with 5 samples.

How the data were processed

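Total RNA of 32D cells carrying 5 FLT3-ITD constructs was labelled with biotin and hybridised to Affymetrix mouse expression arrays, per the labels and the series' design text. The 5 arrays form 5 groups of 1, named by the construct in the labels (ITD78, ITD598, ITD602, ITD611 and ITD613). The title of the ITD602 array carries a different date-like string than those of the other 4, so that run and construct cannot be told apart for it. The labels' protocol gives 3 h of starvation and 1 h of TKI treatment for every array.

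The deposited values are log2 values that the authors made with RMA (background correction, normalization between arrays and 1 summary per probe set), per the submitters' processing notes; the version, software and chip definition were not given in the sources used here. The log base was taken from the values, which run from -0.07 to 13.45, above the natural log of the scanner maximum (11.09). The zero point of the scale is not stated, so differences between arrays were used. The quartiles of the 5 arrays were nearly equal, and 0 columns were left without a sample. Low values are stepped: on each array between 23.7% and 30.3% of the probe sets had a value that at least 100 probe sets of that array shared, and the highest such value was 3.74. Why they are shared is not given in the sources used here. Differences that reach into this range are given as levels and say little about size.

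Of 45101 probe sets, 64 were controls, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9160 were not listed there and stayed unnamed. These classes overlap in 13 control probe sets listed with a gene, which were left out. Gene IDs of 34754 probe sets matched a RefSeq table of the assembly GRCm38.p6, which was used for names only and renamed 0 of them. The probe set with the highest mean over the 5 arrays stood for its gene (18193 genes), and a gene was kept where its highest value was at or above the 60th percentile of all values (2.75), which left 9621 genes. That percentile is itself a shared value, and 44 genes passed by equality, Camp and Fcnb of the neutrophil list, named here after their values were seen, among them.

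With 1 array per construct there are no residual degrees of freedom, and no test was made. For each array, a gene was called set apart where its value lay at least 1 (log2; 2-fold) beyond the nearest of the other 4. Pairs of arrays were described by the genes differing at least 2-fold, the SD of the differences and the correlation over genes. The genes named in the text follow a rule set before the data were examined: per array up to 10 genes with the largest distance above and up to 10 below all other arrays, Flt3 always, up to 4 members with the widest range (at least 2-fold) per gene list, and up to 5 genes per direction for a split by construct number. RIKEN clone genes counted towards these numbers but were left unnamed. Genes named in other ways are said to be so.

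The 23 gene lists, also set before the data were examined, held 365 genes, of which 337 had a probe set and 223 passed the filter. They were STAT5 targets, ERK output and immediate early genes, FOXO targets, MYC and ribosome biogenesis genes, cell cycle genes, BCL2 family, p53 targets, cholesterol synthesis and uptake genes, glycolysis and hypoxia genes, integrated stress response genes, unfolded protein response and heat shock genes, interferon-stimulated genes, antigen presentation genes, inflammatory cytokine and NF-kB genes, neutrophil granule and granulocyte genes, mast cell and basophil genes, monocyte and macrophage genes, erythroid and megakaryocyte genes, lymphoid genes, stem and progenitor genes, cytokine receptor genes, drug transporter genes, and Y-linked genes with Xist. The median difference of a list from the mean of the other 4 arrays was set against 10000 random lists of the same size matched on mean expression in 10 bins. List members were counted as 2-fold higher or lower against that mean, not against every other array. Lists with fewer than 5 members passing the filter were given no percentile.

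The rules were tested on simulated data made from the 9621 genes. All 100 genes shifted by 1.5 and all 100 shifted by 2.5 (log2) on 1 array were recovered, and 4 of 9421 unchanged genes were called. The simulated arrays had the same gene means and a shift on 1 array only, so this recovery does not cover differences that arrays share. On the real arrays ITD613 set apart 215 genes, and 495 without ITD78. With no gene changed and noise drawn from the closest pair of arrays, which also holds any real difference between those constructs, up to 10 genes were set apart on an array. Of the real counts only that of ITD613 exceeded 10. A list of 15 genes raised by 0.5 reached the percentile 100. Of the percentiles of 100 unchanged lists on 5 arrays, 1.6% lay outside the 1st to 99th. These unchanged lists were random genes with independent noise, so this share does not cover lists whose members vary together.

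Alternatives were quantile normalization, cyclic loess, no low-value filter, a filter at the 75th percentile (4.46), a floor at the 40th percentile (1.55), the mean of a gene's probe sets, leaving out probe sets ending in _x_at and _s_at, the median of the other arrays as reference, and leaving out each array in turn. A filter strictly above the 60th percentile and a floor at the highest shared value (3.74) were chosen after seeing the data. Calculations used R 4.3.3 with limma 3.58.1 for cyclic loess, and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, with the random seed 20.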

Results

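Gene expression was measured in 32D cells, a murine myeloid progenitor line that normally depends on interleukin-3, after stable retroviral transduction with 1 of 5 FLT3-ITD constructs. FLT3 is a receptor tyrosine kinase of blood progenitors, and an internal tandem duplication (ITD) makes it signal without its ligand. The labels name the constructs ITD78, ITD598, ITD602, ITD611 and ITD613 and do not say what the numbers mean. Each construct was hybridised to 1 Affymetrix mouse expression array, and per the labels' protocol the cells had been starved for 3 h and then exposed to a tyrosine kinase inhibitor (TKI), not named there, for 1 h. The values were log2 RMA values for 45101 probe sets, with array medians of 2.06 (ITD78), 2.05 (ITD598), 1.99 (ITD602), 2.04 (ITD611) and 1.99 (ITD613). The series compares FLT3-ITD variants with each other. No array without a construct and no replicate array was analysed here, so no difference was tested, no p-value is given, and differences are described by fixed rules of size. An SD printed below is the spread of the other 4 constructs (n = 4 arrays) and not of replicates, and the precision is limited by having 1 array per construct.

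The 5 arrays were first compared in pairs over the 9621 genes that passed the expression filter. ITD598, ITD602 and ITD611 were close to one another, whereas ITD613 differed from each of these 3 in at least 606 genes and ITD78 lay between. Only 12 genes differed at least 2-fold between ITD598 and ITD611, 21 between ITD602 and ITD611, and 25 between ITD598 and ITD602. ITD613 differed at least 2-fold from ITD598 in 606 genes, from ITD611 in 663 and from ITD602 in 797. ITD78 differed in 144 genes from ITD598, in 162 from ITD611, in 249 from ITD602 and in 285 from ITD613. The SD of the log2 differences over genes ran from 0.18 (ITD598 and ITD611; Pearson r over genes 0.996) to 0.63 (ITD602 and ITD613; r over genes 0.952), and genes are not independent replicates. The mouse Flt3 probe set read 1.90, 1.94, 1.90, 1.74 and 1.99 on the ITD78, ITD598, ITD602, ITD611 and ITD613 arrays, below the filter value of 2.75 on each of them. This probe set checks nothing about the constructs, since the labels do not say whether they encode mouse or human FLT3.

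**Figure D1:**
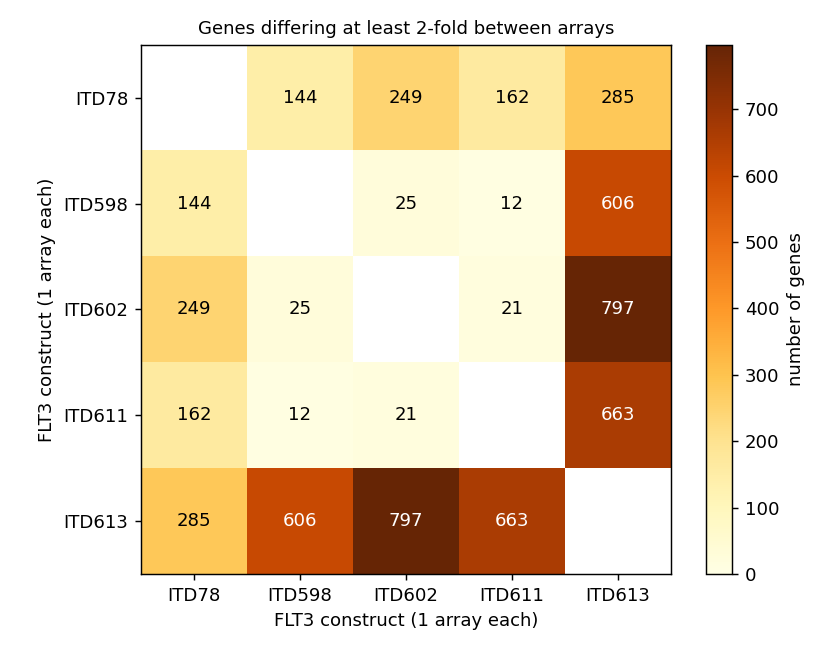
Number of genes, of 9621, whose log2 values differed by at least 2-fold between each pair of arrays; both axes list the 5 FLT3-ITD constructs with 1 array each, and darker cells hold more genes. The pairs among ITD598, ITD602 and ITD611 hold 12 to 25 genes, and the pairs of these with ITD613 hold 606 to 797.

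Mllt3 and Btg2 on the higher side and Cd69 and Tuba8 on the lower side were among the genes furthest from the other arrays on ITD613, and their distances stayed the same with all values below 3.74 raised to that level. Mllt3, a transcriptional regulator fused to MLL in some leukaemias, read 7.76 on the ITD613 array against 2.34 ± 1.77 (SD) on the other 4, where ITD78 was next at 4.97. Btg2, an antiproliferative gene, read 8.08 against 5.05 ± 0.51, and Col5a1, a fibrillar collagen chain, read 9.72 against 6.36 ± 0.95. Mfsd2b, a sphingosine-1-phosphate exporter of red cells and platelets, read 5.41 against 2.59 ± 0.47, and Tspo2, an erythroid membrane protein, read 5.06 against 2.28 ± 0.52. Epx, the eosinophil peroxidase, read 5.18 against 1.90 ± 0.19, and Fcer1a, the IgE-binding chain of the high-affinity IgE receptor, read 3.96 against 0.71 ± 0.03. H3f3b, a histone variant gene, read 6.77 against 4.60 ± 0.13, and Zbtb26 read 3.98 against 1.77 ± 0.21.

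Among the genes lower on the ITD613 array, Cd69, an early activation antigen of leukocytes, read 4.53 against 7.68 ± 0.18 (SD, n = 4 arrays) on the other 4. Pf4 (platelet factor 4) and Selp (P-selectin) read 3.09 against 6.25 ± 0.26 and 2.99 against 5.85 ± 0.29. Ddc, the enzyme that makes dopamine and serotonin from their precursors, read 2.09 against 6.01 ± 0.99, and Tuba8, an alpha-tubulin, read 4.11 against 7.05 ± 0.42. Pdp1, a phosphatase that activates pyruvate dehydrogenase, read 2.97 against 5.72 ± 0.31. Rgs2, a regulator of G-protein signalling, read 3.66 against 6.07 ± 0.41, and the mitotic kinase gene Nek6 read 3.12 against 5.44 ± 0.36. Nap1l3 read 1.37 against 5.00 ± 0.63. Rprd2 read 4.10 against 6.01 ± 0.10 on the probe set used, but only 2 of its 4 probe sets were lower on ITD613, and without probe sets ending in _x_at or _s_at it was higher by 0.69.

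In all, 126 genes were at least 2-fold higher on the ITD613 array than on every other array and 89 were at least 2-fold lower, together 2.23% of the genes. The ITD78 array set these counts: without it they were 271 and 224, which included all 215 genes. With the mean of a gene's probe sets they were 83 and 59. Values below 3.74 lie in a range where many probe sets of an array share 1 value. With lower values raised to that level, 57 genes remained at least 2-fold lower on ITD613. Of the 20 genes with the largest distances on ITD613, 4 then fell short of 2-fold: the distance from the nearest other array was 0.23 for Fcer1a, 0.25 for Zbtb26, 0.33 for Nap1l3 and 0.82 for Ddc, so these differences cannot be sized.

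Gene lists fixed before the data were examined showed lower medians on the ITD613 array of genes for ribosome production, glycolysis and cytokine receptors, and a higher median of cell cycle genes, which went both ways. The 19 MYC and ribosome biogenesis genes had a median difference of -0.45 (log2) from the mean of the other 4 arrays, below all of 10000 random lists of matched expression, and the largest range was that of Wdr43, a ribosome assembly factor (7.44 against 8.46 ± 0.09). The 15 glycolysis and hypoxia genes had a median of -0.41 (percentile 0.030; -0.27 and percentile 0.60 with the mean of probe sets), and 4 were at least 2-fold below the mean of the other 4 arrays. These were Hk2, the hexokinase of the first glycolytic step (5.76 against 7.78 ± 0.41), the glucose transporter gene Slc2a1 (5.98 against 7.19 ± 0.34), the hypoxia-inducible oxygen sensor Egln3 (6.90 against 8.25 ± 0.49) and Ndrg1 (5.32 against 6.69 ± 0.17). On ITD78, Slc2a1 (6.69) and Egln3 (7.53) were within 2-fold of ITD613. The 9 cytokine receptor genes had a median of -0.71, below all random lists, and 4 were at least 2-fold below the mean of the other 4 arrays. Csf2rb2, which encodes a beta chain specific to the interleukin-3 receptor, and Csf2rb, a similar gene for the beta chain common to the receptors for interleukin-3, interleukin-5 and GM-CSF, read 5.12 against 7.06 ± 1.00 and 6.71 against 7.97 ± 0.69. Axl, a receptor tyrosine kinase gene, read 3.28 against 4.32 ± 0.35. The 23 cell cycle genes had a median of 0.25 (percentile 99.99), none of them 2-fold higher, and the G1/S cyclin gene Ccne2 had the widest range (8.24 against 7.55 ± 0.26). Mcm2, Mcm3, Mcm4, Mcm5, Mcm6 and Cdc20, named after their values were seen, were lower, with differences from -0.26 (Mcm2) to -0.07 (Mcm6). The other members were higher. The cytokine receptor median shrank in several settings: it was -0.16 (percentile 1.20) without the low-value filter, -0.25 with low values raised to 3.74 and -0.32 with the mean of probe sets.

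Of the lineage lists, only that of monocyte and macrophage genes lay outside the 1st to 99th percentile on ITD613. Its 7 genes had a median of -0.65 (percentile 0.070), and 3 were at least 2-fold below the mean of the other 4 arrays: Adgre1, which encodes the macrophage antigen F4/80 (2.68 against 5.91 ± 1.96), the high-affinity IgG receptor gene Fcgr1 (3.06 against 5.11 ± 0.86) and Csf1r, the receptor gene for macrophage colony-stimulating factor (2.54 against 3.61 ± 0.33). For Csf1r, 1 of its 2 probe sets had this sign. On ITD78 these 3 genes read 3.00, 3.87 and 3.16, within 2-fold of ITD613. Ctss, a lysosomal protease gene, ranged from 2.62 on ITD78 to 4.10 on ITD602. The 7 erythroid and megakaryocyte genes had a median of 0.42 (percentile 98.8) and went both ways. Klf1 and Gata1, transcription factors of red cell development, read 10.01 against 7.39 ± 0.75 and 8.14 against 6.30 ± 0.51, and Gfi1b, a repressor needed in the same lineages, read 6.87 against 5.77 ± 0.35, while Pf4 was lower. The 7 mast cell and basophil genes had a median of 0.41 (percentile 98.8), with Fcer1a and the carboxypeptidase gene Cpa3 (4.56 against 2.85 ± 0.55) higher and the transcription factor gene Gata2 at 7.22 against 8.11 ± 0.20. The monocyte median was -0.08 (percentile 7.25) without the low-value filter and -0.06 (percentile 7.23) with low values raised to 3.74, and under the stricter filter too few members were left for a percentile.

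ITD78 stood apart by a high level of von Willebrand factor and a low level of the basophil protease gene Mcpt8, and its granulocyte genes were low as a list. The 9 neutrophil granule and granulocyte genes had a median difference of -1.21 from the mean of the other 4 arrays, below all random lists, with 5 at least 2-fold below that mean. Over all members with a probe set, without the low-value filter, the median was only -0.12 (percentile 0.21). Of the 5, Ngp (3.99 on both ITD78 and ITD611) and Mpo (4.52 and 5.00), named here after their values were seen, were not 2-fold below ITD611. S100a8 and S100a9, which encode the calprotectin subunits of neutrophils, read 2.49 against 6.04 ± 1.54 (SD, n = 4 arrays) and 2.11 against values of 3.77 to 7.39 on the other arrays, and Ms4a3, a granulocyte progenitor gene, read 2.63 against 4.75 ± 0.80. Mcpt8 read 2.90 against 5.72 ± 0.26, and Nabp1, which encodes a single-stranded DNA-binding protein, read 3.63 against 5.04 ± 0.27. Vwf (von Willebrand factor) read 6.56 against 3.37 ± 0.42, and Ly6f, a member of a family of similar surface proteins, read 6.07 against 2.49 ± 0.37. Mrvi1, Cltrn and Ckm (muscle creatine kinase) read 5.12, 4.87 and 4.67 against 3.05 ± 0.32, 3.29 ± 0.02 and 3.25 ± 0.26. These 5 genes higher and 5 lower (S100a8, S100a9, Ms4a3, Mcpt8 and Nabp1) were all that ITD78 set apart by 2-fold from every other array. Without the ITD613 array the counts were 41 and 62, and with low values raised to 3.74 there were 2 lower genes, Mcpt8 and Nabp1. S100a9, S100a8 and Ms4a3 then lay 0.03, 0.24 and 0.27 below the nearest array, ITD611, whose own values were close to 3.74, and Ckm lay 0.93 above.

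The 13 p53 targets had a median of -0.36 on the ITD78 array, below all random lists, but none was 2-fold lower, and the median was -0.22 both without the low-value filter and with low values raised to 3.74 (percentiles 0.020 and 0.010). The 7 erythroid and megakaryocyte genes had a median of 0.42 (percentile 99.98), with Klf1 at 8.44 and Gata1 at 7.02, each second to ITD613, and the median was 0.26 without the ITD611 array. The 9 antigen presentation genes, among which no member ranged over 2-fold, had a median of 0.26 (percentile 99.9). Cytokine receptor genes (median -0.29, percentile 0.15) and monocyte and macrophage genes (median -0.29, percentile 0.42) were lower as on ITD613, with Adgre1 at 3.00 and Csf2rb2 at 5.62, but the first percentile moved inside the 1st to 99th in 6 of 14 alternative settings and the second in 5, with too few members for a percentile in 1 more. Both medians were the difference of the same gene, Csf1r, at 3.16 in the low range, and without the low-value filter they were -0.07 and 0.0099. ERK output and cholesterol genes were 0.13 (percentile 99.5) and 0.14 (percentile 99.96) higher in the median. The ERK percentile was 80.1 and the cholesterol percentile 84.1 without the ITD613 array.

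**Figure D2:**
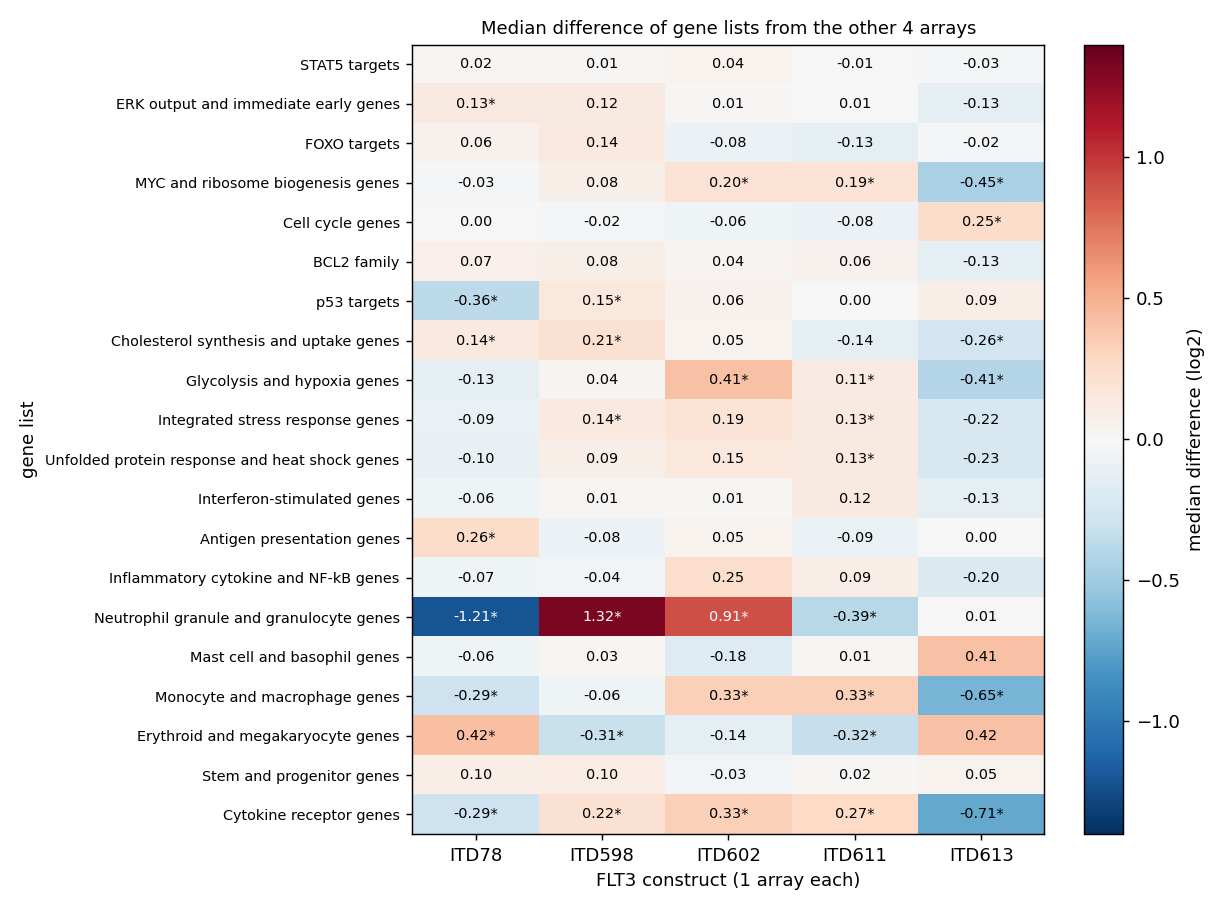
Median log2 difference of each gene list (rows) on each array (columns, 1 array per FLT3-ITD construct) from the mean of the other 4 arrays; red is higher, blue is lower, and * marks medians outside the 1st to 99th percentile of 10000 random lists. The neutrophil granule list runs from -1.21 on ITD78 to 1.32 on ITD598.

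The granulocyte genes S100a8, S100a9 and Ms4a3 were higher on ITD598 and ITD602 than on ITD611. The neutrophil granule list had a median of 1.32 on the ITD598 array and of 0.91 on the ITD602 array, both above all random lists, and of -0.39 on the ITD611 array (percentile 0.010). Without the low-value filter the medians of the neutrophil granule list were smaller, 0.20 on ITD598 and 0.30 on ITD602, and these arrays traded places. S100a9 read 7.39 on ITD598, 6.12 on ITD602 and 3.77 on ITD611, beside 5.67 on ITD613, and S100a8 read 7.61, 6.65, 3.98 and 5.93. Ms4a3 read 5.74, 5.05 and 4.01 on the same 3 arrays, while the granule protease gene Ctsg was high on each of them (9.09, 9.17 and 8.77, against 7.42 on ITD78 and 6.24 on ITD613). ITD598 set apart 2 genes by 2-fold, both higher: S100a9 and Stfa3, a stefin A cysteine protease inhibitor gene (3.12 against 1.29 ± 0.27), whose values all lie in the low range below 3.74. Without the ITD602 array there were 6 higher and 1 lower. The ITD611 percentile was 48.0 without the ITD598 array, 5.80 without the ITD602 array, 24.0 without the low-value filter and 1.66 without probe sets ending in _x_at or _s_at.

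On the ITD602 array 4 globin genes were at least 2-fold lower than on every other array. The embryonic globin genes Hba-x, Hbb-bh1 and Hbb-y read 5.44 against 8.82 ± 2.23 (SD, n = 4 arrays), 6.85 against 9.45 ± 1.26 and 10.31 against 12.12 ± 0.70, and the adult globin gene Hbb-b2 read 5.18 against 7.69 ± 0.96. Globin genes are similar in sequence, and the beta-type probe sets used can bind more than 1 of them. Zfp62 and Zfp982, which encode zinc finger proteins, read 3.66 against 5.22 ± 0.44 and 4.83 against 6.03 ± 0.09. With the mean of a gene's probe sets the Hbb-b2 difference was -0.87, and without probe sets ending in _x_at or _s_at the Zfp982 difference was -0.11. With a RIKEN clone gene, which was not apart with low values raised to 3.74, these made 7 genes lower, and none was higher by 2-fold; without the ITD611 array 11 were lower, and with the mean of probe sets 4. Glycolysis and hypoxia genes had a median of 0.41 on ITD602, above all random lists, but 0.28 without the low-value filter or with the mean of probe sets and 0.26 (percentile 99.94) against the median of the other arrays. MYC and ribosome biogenesis genes had a median of 0.20 (percentile 99.6; 97.1 without the ITD613 array). The ITD602 array also differed from the others in a hybridisation control: the spiked-in bioB transcript read 6.10 there against 2.61 ± 0.20. The other arrays read 2.43 to 2.83, in the low range, so this distance cannot be sized. Whether the reading on ITD602 or those on the other arrays are unusual was not tested.

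ITD611 set no gene apart by 2-fold from all other arrays, in either direction. The counts of genes set apart on ITD78, ITD598 and ITD602 did not exceed 10, the most set apart on an array in simulated data with no changed gene. The spread of these data came from the closest pair of constructs and includes any real difference between them, and single large distances such as those of Ly6f and Vwf are not judged by this count. For ITD78 the count is also held down by ITD613: without that array ITD78 set apart 41 genes higher and 62 lower. Its low count is therefore no sign that ITD78 was unchanged. MYC and ribosome biogenesis genes had a median of 0.19 on ITD611 (percentile 99.99; 0.08 without the ITD613 array), and erythroid and megakaryocyte genes one of -0.32 (percentile 0.040), with Klf1 at 7.08 and Gata1 at 6.05. The same erythroid list had a median of -0.31 on ITD598 (percentile 0.010), where the percentile was 15.6 without the ITD613 array; on ITD611 it was 2.03 without the low-value filter. Monocyte and macrophage genes had a median of 0.33 on both ITD602 and ITD611 (percentiles 99.4 and 99.98), with Adgre1 at 7.21 and 6.91, and cytokine receptor genes were higher in the median on ITD598 (0.22), ITD602 (0.33) and ITD611 (0.27). Each 0.33 was the difference of the same gene, Csf1r, at 3.66 in the low range. Without the low-value filter the monocyte medians were 0.10 and 0.02. The cytokine receptor medians were then 0.07, 0.08 and 0.002, and all 5 lay inside the 1st to 99th percentile. Without the ITD613 array, all of these monocyte and cytokine receptor medians lay inside the 1st to 99th percentile. The poly-A spikes dap, phe, lys and thr were each highest on ITD611. There dap read 6.37 against 5.42 ± 0.22, and phe, lys and thr, in or near the low range, read 3.87, 3.69 and 3.55 against 3.04 ± 0.23, 2.97 ± 0.20 and 2.95 ± 0.19. The 18S ribosomal RNA control read 9.20 there against 8.32 ± 0.14. The 3' minus 5' differences, which grow as RNA degrades, were also the highest of the 5 arrays on ITD611, at 1.56 against 1.26 ± 0.10 for beta-actin and 0.59 against 0.38 ± 0.12 for Gapdh.

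**Figure D3:**
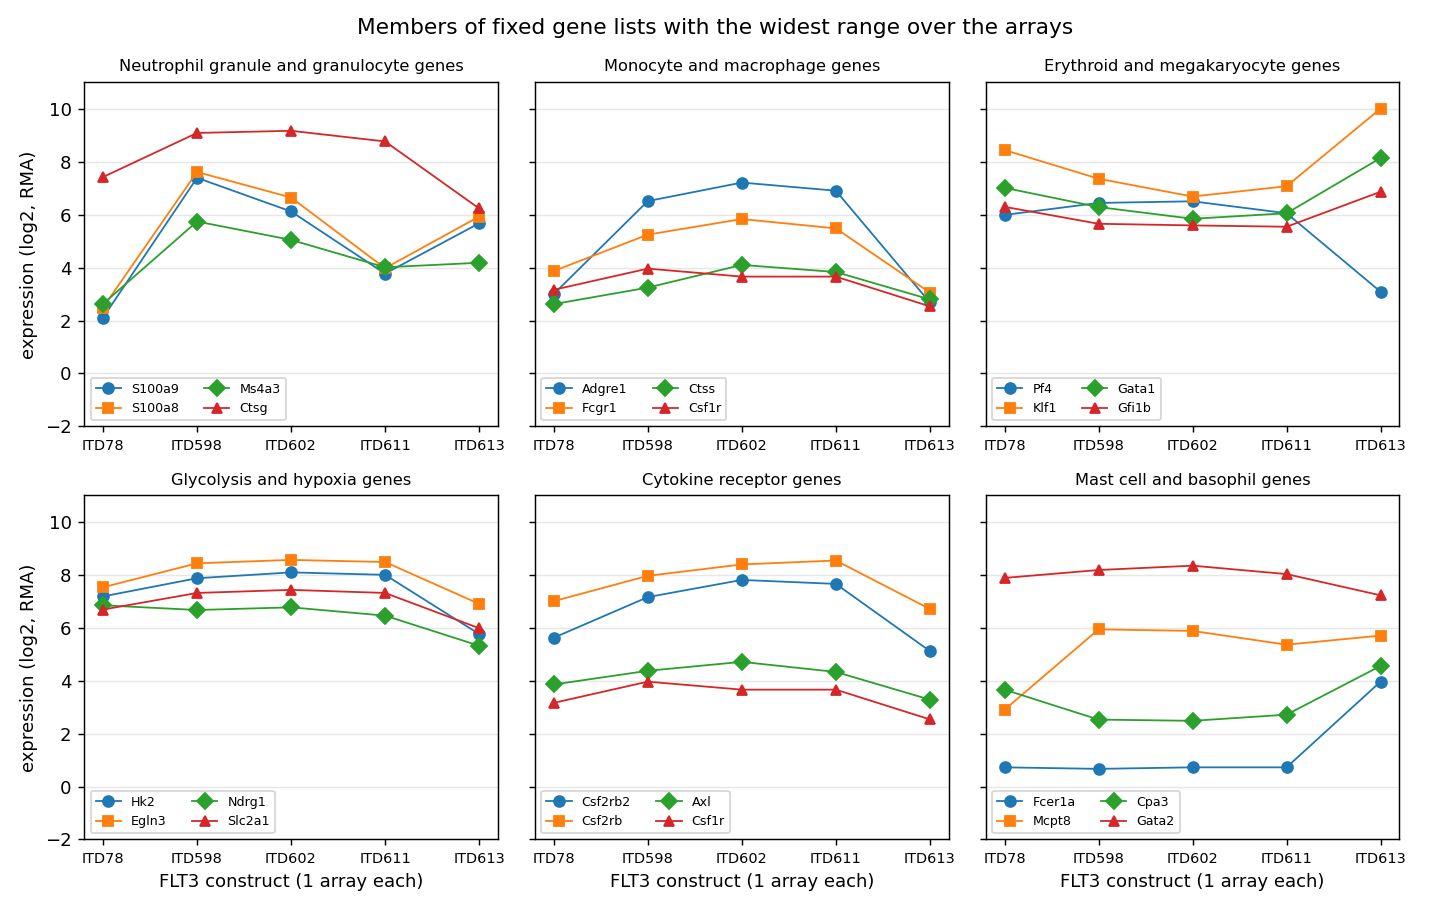
Log2 RMA values (vertical axis) of the up to 4 widest-ranging members of 6 fixed gene lists on the 5 arrays (horizontal axis, 1 array per FLT3-ITD construct); each point is 1 array, the lines only join points of a gene, and no replicate error exists. S100a8 and S100a9 run from 2.49 and 2.11 on ITD78 to 7.61 and 7.39 on ITD598, and Klf1 is highest on ITD613 at 10.01.

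Among genes downstream of FLT3 signalling, single members differed at least 2-fold between arrays. All levels are those after starvation and TKI exposure, and no array without TKI was analysed here. They therefore do not measure the signalling strength of the constructs. The 16 STAT5 targets had medians between -0.03 and 0.04 on the 5 arrays, none outside the 1st to 99th percentile, and 4 members ranged over at least 2-fold. These were Il2ra, the alpha chain gene of the interleukin-2 receptor (4.30 on ITD602, 1.90 on ITD613), the kinase genes Pim1 (8.98 and 7.91 on the same arrays) and Pim2 (4.16 and 2.97), and the D-type cyclin gene Ccnd3 (6.60 on ITD611, 7.71 on ITD613). With low values raised to 3.74, Il2ra and Pim2 ranged over only 0.56 and 0.42. Among 13 ERK output and immediate early genes, the median on ITD613 was -0.13 (percentile 8.97). The transcription factor gene Etv5 (4.55 against 5.87 ± 0.15) and the feedback inhibitor gene Spry2 (3.91 against 4.85 ± 0.15) were lower there, Egr2 (1.98 against 3.01 ± 0.09) lay in the low range on every array, and Phlda1 was higher (6.74 against 5.06 ± 0.33). The 6 FOXO targets had medians between -0.13 and 0.14, and the atypical cyclin gene Ccng2 was higher on ITD613 (6.12 against 4.37 ± 0.44), so that the median (-0.02) and the mean (0.25) differed in sign there. In the BCL2 family (9 genes, medians between -0.13 and 0.08), the survival gene Bcl2 read 5.69 on ITD613 against 7.11 ± 0.29, and the BH3-only gene Pmaip1 read 4.52 against 5.49 ± 0.19. On ITD613 the p53 targets Trp53inp1 (6.52 against 4.44 ± 0.21) and Polk, a translesion polymerase gene (5.89 against 4.47 ± 0.21), were higher and Pmaip1 and Eda2r, a receptor gene in the low range (1.46 against 2.43 ± 0.36), were lower, with a list median of 0.09 (percentile 78.7).

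Members of the integrated stress response list differed in opposite directions on ITD613. Among 13 integrated stress response genes, 8 ranged over at least 2-fold. The serine synthesis gene Phgdh (7.21 against 8.97 ± 0.37) and the asparagine synthetase gene Asns (7.18 against 8.16 ± 0.26) were lower on ITD613, while Trib3 (6.36 against 5.11 ± 0.23) and Ddit3, which encodes the transcription factor CHOP (5.68 against 4.55 ± 0.39, with this sign in 1 of 2 probe sets), were higher. The list's medians were -0.22 on ITD613 (percentile 2.57), 0.14 on ITD598 (99.3) and 0.13 on ITD611 (99.4), and the percentiles of ITD598 and ITD611 moved inside the 1st to 99th in 9 and 4 of 14 alternative settings. Cholesterol genes had a median of 0.21 on ITD598, above all random lists, and of -0.26 on ITD613 (0.74, lost in 5 of 14 settings), and Hmgcs1, an early enzyme of the pathway, read 9.48 and 8.30. Unfolded protein response and heat shock genes had a median of 0.13 on ITD611 (percentile 99.2, lost in 6 of 14 settings), and the chaperone gene Pdia4 ranged from 5.06 on ITD613 to 6.08 on ITD602. p53 targets had a median of 0.15 on ITD598 (percentile 99.8), and glycolysis genes one of 0.11 on ITD611 (99.04), lost in 4 and 8 of 14 settings.

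The remaining lists did not leave the 1st to 99th percentile on any array. Interferon-stimulated genes (5 members) had medians between -0.13 and 0.12, and no member ranged over 2-fold. Of 7 inflammatory cytokine and NF-kB genes, the interleukin-6 gene Il6 was higher on ITD613 (5.43 against 3.28 ± 0.34) and the chemokine gene Ccl3 read 1.92 on ITD78 and 2.87 on ITD613 against 4.93 on ITD602, and on ITD613 the median (-0.20) and mean (0.11) differed in sign. The 9 stem and progenitor genes had medians between -0.03 and 0.10, with Mecom at 10.14 and Lmo2 at 10.52 on ITD613 against 9.30 ± 0.29 and 9.63 ± 0.33, and Erg at 1.88 there against 2.94 ± 0.26, in the low range. Runx1 read 4.03 on ITD613 against 5.12 ± 0.24, but with the mean of its probe sets the difference was 0.097. Fewer than 5 members of the drug transporter list (4) and the lymphoid list (3) passed the filter, too few for a percentile. The efflux pump gene Abcb1b read 3.18 on ITD613 and 4.76 on ITD78, against 6.49, 6.34 and 6.42 on ITD598, ITD602 and ITD611, and no lymphoid gene ranged over 2-fold. No probe set of Xist or of a Y-linked gene passed the filter. Of 100 percentiles over 20 lists, 33 lay outside the 1st to 99th, against 2 for lists of randomly drawn genes. Members of a gene list may vary together and some lists share members, so this 2 is not what chance would give for them. The values of the 5 arrays also depend on each other, since each array is part of the reference of the other 4. In at least 1 of the 14 alternative settings, 28 of these 33 medians were over 1.5 times smaller than reported or of the other sign. Of 52 list members with the widest ranges, 10 ranged over less than 2-fold with low values raised to 3.74: Il2ra, Pim2, Egr2, Eda2r, Cpa3, Fcer1a, Csf1r, Ctss, Erg and Axl. Median and mean differed in sign for 18 of the 100 and for 0 of the 33.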

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

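The alternatives were set before the data were examined, apart from the strict filter and the floor at 3.74, which were chosen after seeing the data. No paired analysis was possible because each construct had 1 array and no result came from a test. Counts under quantile normalization, cyclic loess, no low-value filter, the floor at the 40th percentile, the strict filter and without _x_at and _s_at probe sets were within 1.5 times the reported ones. With the mean of probe sets, ITD613 had 83 genes higher and 59 lower, 132 of these 142 among the reported 215, ITD602 had 4 lower, ITD598 and ITD602 differed in 14 genes, and ITD78 and ITD613 in 186. At the 75th percentile filter, ITD598 had 1 gene higher, ITD598 and ITD611 differed in 7 genes, and the split by construct number separated 1 gene, as fewer genes remained. With the floor at 3.74, ITD613 had 57 genes lower, ITD78 had 2 lower, ITD598 had 1 higher, the number split separated 1, and the pairs differed in 16 (ITD598 and ITD602), 7 (ITD598 and ITD611), 84 (ITD78 and ITD598), 96 (ITD78 and ITD611) and 182 genes (ITD78 and ITD613), since differences below the floor are removed. For the other changes the cause was not tested.

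With 1 other array left out at a time, ITD78 and ITD613 moved each other's counts most. The ITD613 counts were 129 to 271 higher and 91 to 224 lower, the upper ends without ITD78. Those of ITD78 were 5 to 41 higher and 5 to 62 lower, the upper ends without ITD613. ITD598 had 2 to 6 higher and 0 to 1 lower, with the upper ends without ITD602, ITD602 had 0 to 2 higher and 7 to 11 lower, and ITD611 had 0 to 1 higher and 1 to 3 lower. Of the 33 list medians outside the 1st to 99th percentile, 12 stayed outside in all 14 alternatives: granulocyte genes on ITD78, ITD598 and ITD602, MYC and ribosome biogenesis genes on ITD611 and ITD613, glycolysis genes on ITD602 and ITD613, cell cycle genes on ITD613, p53 targets, erythroid and antigen presentation genes on ITD78, and cholesterol genes on ITD598. Their sizes still moved: in the setting with the smallest median they were -0.12, 0.20 and 0.30 (granulocyte genes), 0.08 and -0.38 (MYC), 0.25 and -0.27 (glycolysis), 0.17 (cell cycle), -0.22, 0.26 and 0.20 (p53 targets, erythroid and antigen presentation genes) and 0.16 (cholesterol), in the same order. The other 21 moved inside in at least 1 or had too few members for a percentile. List medians moved by less than 1 SD of the random lists in 321 comparisons and by more in 140, and the monocyte list on ITD78 turned to 0.0099 without the low-value filter. Differences of named genes moved by less than the SD of the other 4 arrays in 1106 comparisons and by more in 65. Rprd2 on ITD613 turned to 0.69 without _x_at and _s_at probe sets and Runx1 to 0.097 with the mean of probe sets, where their probe sets differ in sign. Values below 3.74 limit what can be ordered, since many probe sets share them.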

Other observations

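The tests in this part were chosen after the result was seen, apart from the split by construct number, which was planned but whose reading was set afterwards. The genes in the next 2 paragraphs were chosen after their values were seen, except where the rule of the report also names them.

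The red cell genes named next were picked because they were highest on the ITD613 array and second on ITD78, so they are no list and no test. Some of them were also high on the other 3 arrays, and values below 3.74 cannot be sized. Hba-x, the embryonic alpha-type globin, read 11.27 on ITD613 and 10.13 on ITD78, against 7.13 on ITD598, 6.73 on ITD611 and 5.44 on ITD602, a range of 56.9-fold, and Hbb-bh1 read 10.87, 10.13, 8.65, 8.16 and 6.85 in the same order. Slc4a1, the band 3 anion exchanger of the red cell membrane, read 5.55 on ITD613 and 4.91 on ITD78 and at most 1.41 on the other 3 arrays. Rhag, a red cell membrane channel gene, read 5.70 and 5.38 against at most 3.37, and the membrane skeleton gene Epb42 read 4.75 and 3.32 against 1.88 on each of the other 3. The transcription factor genes Nfe2 (8.23 and 7.49) and Tal1 (9.53 and 8.96) were also highest on these arrays, at most 6.75 and 8.46 on the others. Prg2, the eosinophil major basic protein, read 4.17 on ITD613 beside Epx, but 3.47 on ITD598 and 1.53 on ITD78.

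Ifitm1, an interferon-inducible membrane protein gene that is not in the interferon list, went the other way, at 8.86, 9.74 and 9.17 on ITD598, ITD602 and ITD611 against 6.22 on ITD78 and 6.47 on ITD613. Ifitm3 read 8.21, 8.81 and 8.16 against 7.04 and 7.25, whereas Ifitm2 ranged over only 0.46. The Myc transcript read 8.34 on ITD613 and between 7.37 and 7.47 on the other 4 arrays, while the MYC and ribosome biogenesis list was lower on ITD613. Among 2646 probe sets without a single gene name that passed the filter, ITD613 set 52 apart as higher and 33 as lower, and no other array more than 3 in a direction.

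ITD613 stood apart from the other 4 arrays with 126 genes higher and 89 lower. The spike controls gave no sign of a difference of hybridisation or labelling, since none lay beyond the nearest other array on ITD613 (largest distance -0.0195). They cannot exclude it: bioB on ITD602 and dap on ITD611 lay 3.27 and 0.81 beyond the nearest array, yet these arrays differed in only 21 genes. The bioB distance starts in the low range below 3.74 and cannot be sized. Degraded RNA as the whole cause is argued against by the 3' minus 5' differences of Gapdh and beta-actin. These were 0.56 and 1.41 on ITD613, above ITD78, ITD598 and ITD602 (at most 0.34 and 1.25) but below ITD611 (0.59 and 1.56; distance -0.0348), and ITD611 differed from ITD598 in only 12 genes. For values proportional to RNA amounts, RNA of other cells below an equal share lowers no gene 2-fold by dilution. Yet 89 genes were lower, and 57 with low values raised to 3.74. A larger share was not tested, and whether the values are proportional is not known. The clone or passage history of the transduced culture stays open and cannot be told apart from the construct, since there was 1 array per construct, and that the construct itself raises the red cell genes named above is a hypothesis that may be tested with further cultures.

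ITD78 shared part of the ITD613 differences: with a different reference array on each side they correlated over genes with r between 0.58 and 0.64 (covariances between 0.11 and 0.15), beside 0.66 to 0.75 with a shared reference, which argues against noise of a single shared reference array as the whole cause. The 3 reference arrays are close to each other (r over genes at least 0.993), so a departure common to them would give the same values and stays open. Of 87 genes at least 4-fold from ITD598, ITD602 and ITD611 on ITD613, 75 lay between on ITD78. If ITD78 were a mixture of ITD613 cells with cells at the levels of ITD598, ITD602 and ITD611, 1 share would account for both directions. A mixture with cells of a different profile need not give 1 share and was not tested. A share also takes the deposited values as proportional to RNA amounts, which is not known here, and low values are stepped. The shares given next therefore cannot exclude a mixture. The implied median share was 21.0% over the 41 higher genes (quartiles 12.6 and 39.7) but 77.0% over the 46 lower genes (58.3 and 90.1), a difference of 56.0 percentage points. At 2-fold the medians were 24.0% over 271 and 60.3% over 224 genes; this share replaced, after both had been seen, a count of 10 genes set apart on ITD78, which simulated data with no changed gene also reached, and what ITD78 and ITD613 have in common was not tested.

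The globin genes Hba-x, Hbb-bh1, Hbb-y and Hbb-b2 were lowest on the ITD602 array, and so were Klf1 (6.68) and Gata1 (5.84). A separate hybridisation run of this array cannot be told apart from its construct: the bioB spike lay 3.27 (log2) beyond the nearest other array, while its bioC, bioD and cre spikes lay at most 0.03 beyond it. The bioB readings of the other arrays lie in the low range below 3.74, so 3.27 does not size a run difference. A run difference may therefore add to the globin values, and no second ITD602 array was analysed here.

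A split by construct number separated 3 genes by at least 2-fold, each higher on ITD598 and ITD602 than on ITD611 and ITD613: Stfa2l1 (3.51 and 2.59 against 1.22 and 1.22), Gem (2.72 and 2.72 against 1.496 and 0.83) and Mpo, the myeloperoxidase gene (6.55 and 6.21 against 5.00 and 5.18). The split was planned without ITD78, the lowest number. There Mpo (4.52) was the lowest of the 5 arrays, against an order by number. All values of Stfa2l1 and Gem lie below 3.74, where levels cannot be ordered, and with low values raised to 3.74 only Mpo was separated. The 2 other pairings of the 4 arrays separated 0 and 1, and 3 pairings are too few for a share under 0.05.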
